A study of Halocynthia roretzi with 24 samples.

How the data were processed

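Expression was measured by RNA sequencing in 24 libraries of *Halocynthia roretzi*, 4 for each of the animal hemisphere, the vegetal hemisphere and the whole embryo at 8 and at 110 cells. Per the labels' protocols, total RNA was taken up in Trizol, libraries were made with an Illumina TruSeq RNA kit, and the libraries of hemispheres and whole embryos did not keep strand. Per the submitters' processing notes, HISAT2 was used, with no version given. The genome build, the read counter and the treatment of reads with several matches are not given in the sources used here. The authors deposited RPKM values, reads per kilobase of gene model and M (mega) reads, for 16078 gene models and an annotation of 16082 gene models on numbered scaffolds. RPKM multiplied by the exon length of each model in kilobases summed to 1.012 to 1.032 M per library, so the deposited RPKM values are relative to reads in genes. RPKM is a share of each library, so a change in the total RNA per embryo cannot be seen.

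Depth was inferred from the RPKM values. The step that stands for 1 read was fitted in each library to low values multiplied by exon length, and 71% to 82.9% of these values lay within 0.1 reads of a whole number, where 20% would by chance. This recovers reads only approximately, so no count model was used. The inferred depth was 3.09 to 9.07 M reads in genes. A floor of 3 reads amounted to 0.221 to 0.648 RPKM for a gene with 1.5 kb of exons, and covers counting error only. No pair of libraries held the same values.

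Of the gene models in the expression table, 11435 had a note naming a best match that starts with KH, 643 a protein record and 3999 no match, and 1 table identifier had no annotation. The files do not explain the KH identifiers, and no reference genome was used. Of 14 gene lists, 1 had a gene that could be matched, the model whose note names ND5, and no list reached the 5 members needed for a set test. For that reason at most 2 identifiers that rose and 2 that fell are named per comparison, those with the largest log2 change among genes with adjusted p under 0.05, a mean of at least 5 RPKM in the higher group and, for comparisons of 2 groups, no overlap between their libraries. Genes named outside this rule are said to have been chosen after their values were seen.

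Tests were made with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with genes at 1 RPKM or more in at least 4 libraries (12703 genes). All 24 libraries entered 1 fit with 6 groups, moderated with a trend in the prior variance, and p-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on this scale understates the change of low genes, and folds given without log2 are ratios of mean RPKM. The comparisons, the test, the samples in the fit, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The expression classes, the group of scaffold S964, the genes sharing a best match and the genes above both hemispheres were defined afterwards. Genes were called above both hemispheres when whole embryos were higher at an adjusted p under 0.05 against each hemisphere. Sets were tested with camera, with a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the sets of a comparison. The animal share was the slope through the origin of whole minus vegetal on animal minus vegetal RPKM within a replicate number, over genes called regional in the other numbers.

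Replicate numbers come from the labels, which do not say what they mark. Deviations from the group means of same-numbered libraries were correlated across genes. They correlated at 0.37 to 0.58 between animal and vegetal libraries at 8 cells, at 0.40 to 0.49 at 110 cells, at 0.13 to 0.47 between the stages in animal and 0.15 to 0.37 in vegetal hemispheres, and at 0.39 or more between whole embryos and either hemisphere of a stage. Each of these pairs was over 0.1, so the numbers were taken to pair the libraries in those comparisons, and values with the number as a block are given beside a result where they move its count by over 1.5 times.

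The fit was tested on simulated values. Every library, also those of 110 cells, was given the mean of the 8-cell groups for each gene, with independent noise of the gene-wise spread of the data. Changed genes were drawn from those at 5 RPKM or more. The simulation held no 110-cell levels and no pairing by replicate number, so recovery in the data may differ. In each comparison 12703 genes were run, and of 50 genes changed 2-fold and 50 changed 4-fold it recovered 50% and 100% for the hemispheres at 8 cells, 58% and 94% for the hemispheres at 110 cells, 76% and 96% for the stages in whole embryos, 48% and 90% in animal and 66% and 88% in vegetal hemispheres, and 44% and 76% for the change between stages. For whole embryos against the hemispheres it recovered 62% and 98% at 8 cells and 80% and 100% at 110 cells. The alternatives were other pseudocounts (0.1 and 5 RPKM), no filter, a filter of 5 RPKM, median-ratio rescaling, quantile normalization, the replicate block, a fit of the compared groups alone, a robust prior, no trend, a 2-fold minimum and leaving out libraries and replicate numbers. Figures were drawn with matplotlib.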

Results

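RNA sequencing was carried out on embryos of the ascidian *Halocynthia roretzi*, a solitary tunicate, at the 8-cell and the 110-cell stage. At each stage the animal hemisphere, the vegetal hemisphere and the whole embryo were each represented by 4 libraries numbered 2 to 5, which gave 24 libraries in 6 groups. The series set out to compare expression between regions of the embryo and between the stages. The labels do not say how or when the hemispheres were separated, nor whether a number stands for a separate batch of embryos, so the p-values measure the spread between these libraries. Expression was given as RPKM for 16078 gene models, of which 12703 passed the filter on low values. The steps between low RPKM values placed the depth at about 3.09 to 9.07 M (mega) reads in genes per library, with a median of 5.68 M. Vegetal libraries had the lowest mean depth of each stage, at 4.76 ± 1.36 M reads at 8 cells and 4.36 ± 0.775 M at 110 cells (SD, n = 4), against 7.47 ± 1.19 and 6.39 ± 0.858 M in animal libraries. The deposited files pair gene models with identifiers of their best protein match and not with gene names, so genes are given by the identifiers in the files, with positions on the numbered scaffolds of the deposited annotation.

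Stage separated the libraries most on the principal components, and region separated them at 110 cells. The first principal component held 40.4% of the variance and parted the 12 libraries of each stage, and the second held 12% and ordered the 110-cell libraries from animal through whole to vegetal. Libraries of the same group had Spearman correlations of 0.919 to 0.969 across genes. Animal and vegetal libraries of the 8-cell stage correlated at 0.951 to 0.984, and those of the 110-cell stage at 0.869 to 0.934 (median 0.902). Libraries of different stages correlated at 0.852 to 0.945 (median 0.898). These pairs include libraries of different regions, so this range cannot be set against that of region alone. These correlations are across genes, which are not independent replicates.

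**Figure D1:**
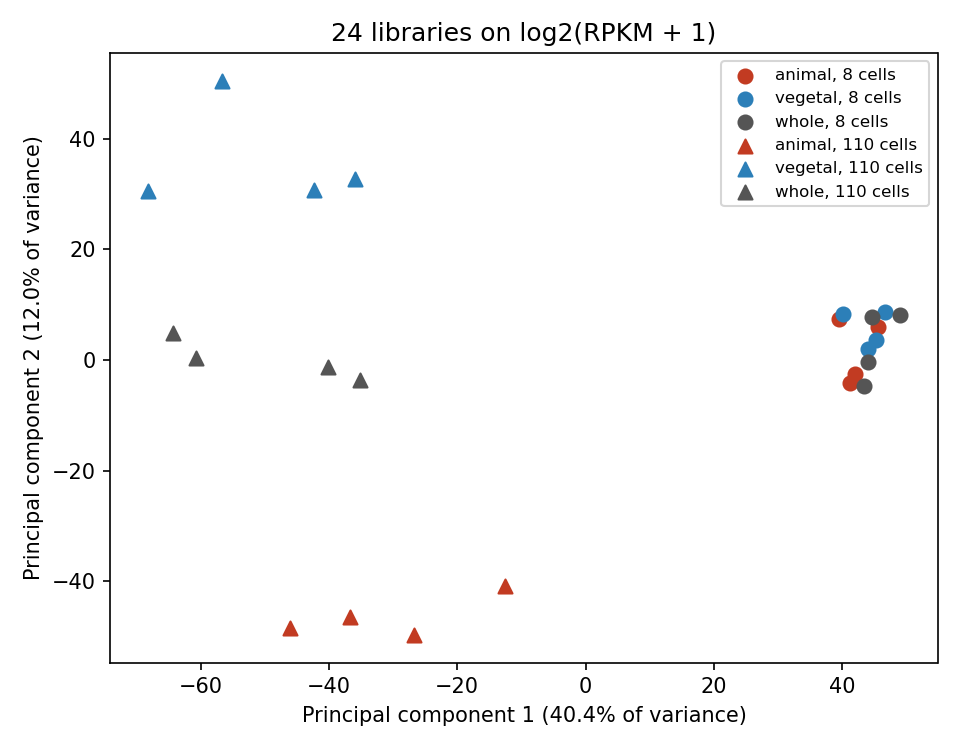
Principal components 1 and 2 of log2(RPKM + 1) over the 12703 tested genes, 1 point per library, with colour for region and shape for stage. The 8-cell libraries lie together at the right, and the 110-cell animal, whole and vegetal libraries form separate bands along the second component, which holds 12% of the variance.

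At the 8-cell stage few transcripts were called between the animal and vegetal hemispheres, and all 15 genes called in the main fit were higher in the vegetal hemisphere. Harore.CG.MTP2014.S480.g12062 stood at 422 ± 23.8 RPKM in vegetal and 61.1 ± 14.9 RPKM in animal hemispheres (SD, n = 4), a 6.92-fold difference (log2 animal over vegetal -2.80 ± 0.32 SE, limma adjusted p = 3.29e-05). Harore.CG.MTP2014.S480.g14149, whose note names KH.C1.755 as best match, stood at 806 ± 138 and 131 ± 24.9 RPKM, a 6.17-fold difference (log2 -2.62 ± 0.22 SE, adjusted p = 3.9e-07). These models overlap on opposite strands of scaffold S480, from 9248 to 10663 and from 10488 to 16473, and the libraries do not keep strand, so their reads cannot be fully told apart. Across the 15 genes the vegetal level was 1.59 to 6.92 times the animal level. All 15 were also called vegetal-higher at 110 cells, both over all genes and adjusted over the list alone, and none had a called change of the regional difference between stages. The list was chosen on the 8-cell libraries, whose numbers pair them with the 110-cell libraries, so the counts are not independent evidence.

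The gene models of scaffold S964 formed a group that was higher in the vegetal hemisphere at both stages. This scaffold was singled out after its values were seen, because 2 of the 15 genes lie on it. It carries 11 models, all on the plus strand, between positions 1033 and 14372, and the note of Harore.CG.MTP2014.S964.g01698 names ND5, a subunit of respiratory complex I that animal mitochondrial genomes encode. That model, from 6139 to 6998, stood at 2608 ± 854 RPKM in vegetal and 870 ± 232 RPKM in animal hemispheres at 8 cells, and at 2854 ± 1480 and 1149 ± 403 RPKM at 110 cells (SD, n = 4), without a call of its own at either stage (adjusted p = 0.643 and 0.106). All 10 tested models had higher vegetal means, 2.02 to 3.31 times the animal means at 8 cells and 2.44 to 3.61 times at 110 cells. Their mean log2 value was lower in animal than in vegetal hemispheres in 4 of 4 numbers at each stage, with an animal minus vegetal difference of -1.35 at 8 cells and -1.56 at 110 cells (two-sided exact permutation p = 0.125 at each stage on the 4 same-numbered differences). That is the smallest p that 4 pairs allow, so this test cannot pass 0.05, and with the libraries taken as unpaired the exact permutation p was 0.0286. At 8 cells 2 of the 10 were called over all genes and at 110 cells 9 of 10, and adjusted over the list alone 10 of 10 at each stage. The set test camera gave an adjusted p = 0.000183 at 8 cells and 0.0267 at 110 cells with an estimated correlation (0.000102 and 0.0118 with the replicate number as a block), for a group chosen on these libraries. None of the 10 changed between stages in whole embryos.

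**Figure D2:**
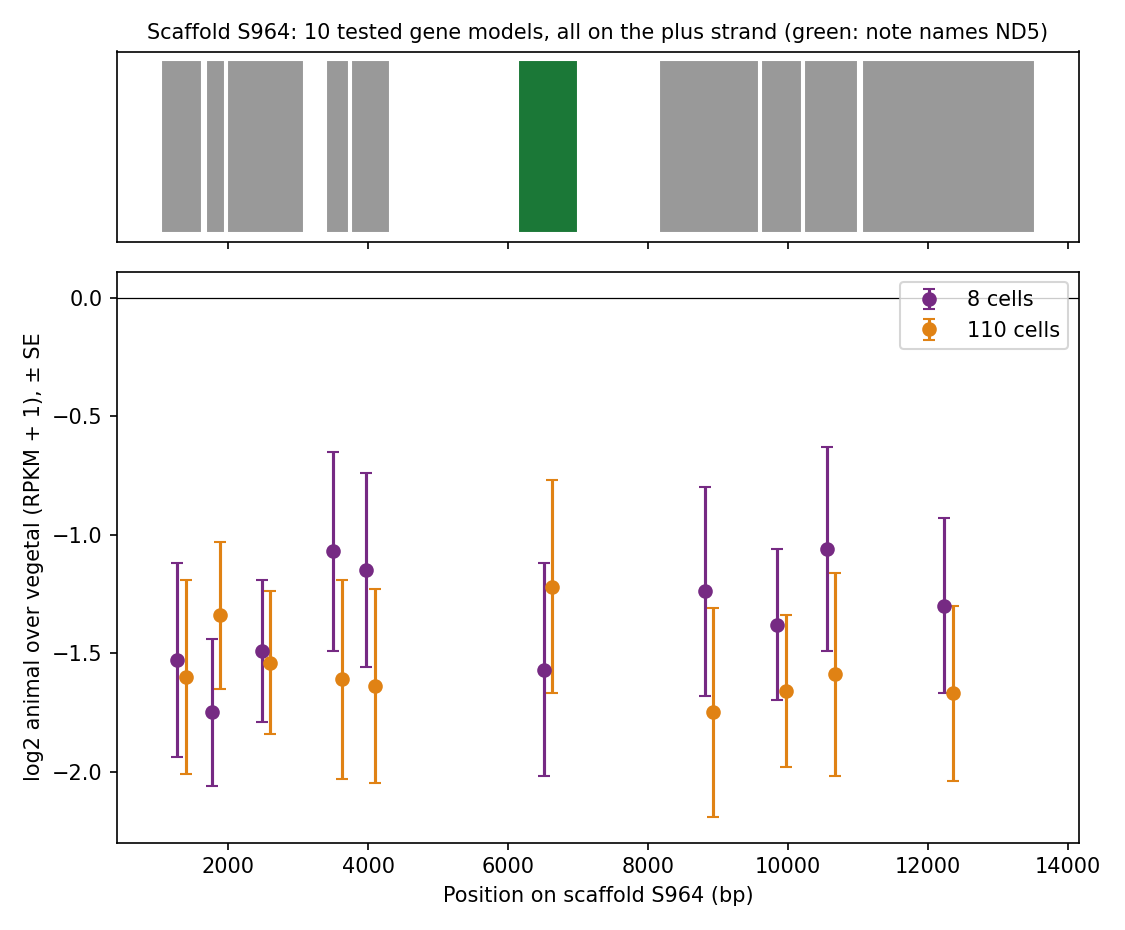
The 10 tested gene models of scaffold S964 by position in base pairs (top) and the log2 animal over vegetal difference of each with its SE at both stages (bottom). All 10 tested models lie below 0 at 8 cells and at 110 cells.

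The 8-cell test was run with limma over 12703 genes, of which 345 had an unadjusted p under 0.05, 199 of them higher in animal and 146 in vegetal hemispheres. That is a smaller share than the 0.05 that would arise without any difference. The few calls of this fit therefore need not mean that few transcripts differ. It had no block for the replicate number, so deviations shared by same-numbered animal and vegetal libraries (correlations of 0.37 to 0.58) counted as spread. With the replicate number as a block 39 genes were called, 6 animal-higher and 33 vegetal-higher, and without replicate 3 or 5 of every group 7 and 9 were called. A fit of these groups alone called 11 genes, 1 animal-higher and 10 vegetal-higher, of which 8 were among the 15. With a pseudocount of 0.1, 17 genes were called, 2 animal-higher and 15 vegetal-higher. On simulated values the main fit recovered 50% of 2-fold and 100% of 4-fold changes in this comparison.

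At the 110-cell stage the hemispheres differed in 1163 genes, 463 higher in the animal and 700 higher in the vegetal hemisphere. Harore.CG.MTP2014.S182.g13272 (36269 to 38720, best match KH.C2.957) stood at 139 ± 20 RPKM in animal and 5.02 ± 4.56 RPKM in vegetal hemispheres (SD, n = 4), a 27.8-fold difference (log2 4.78 ± 0.39 SE, adjusted p = 2.85e-09). Harore.CG.MTP2014.S201.g08639 (127747 to 129546, KH.C4.71) stood at 193 ± 89 and 12.4 ± 14.9 RPKM (log2 4.67 ± 0.66 SE, adjusted p = 1.36e-05). In the vegetal direction, Harore.CG.MTP2014.S104.g10185 (229361 to 231074, KH.C6.217) stood at 172 ± 73.3 RPKM against 1.51 ± 0.514 RPKM in animal hemispheres, a 114-fold difference (log2 -6.03 ± 0.35 SE, adjusted p = 1.46e-11). Harore.CG.MTP2014.S31.g00819 (110877 to 111266), with no match named, stood at 131 ± 29.6 against 0.424 ± 0.491 RPKM (log2 -6.57 ± 0.36 SE, adjusted p = 5.12e-12).

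Of 483 genes with group means below 1 RPKM at 8 cells and at least 5 RPKM in a 110-cell group, 153 were animal-higher and 241 vegetal-higher, or 81.6% with a regional call. The median log2 difference of these regional genes was 2.41 in the animal and -3.14 in the vegetal direction. Of 8918 genes at 5 RPKM or more in every 8-cell group, 153 were animal-higher and 135 vegetal-higher, or 3.23%, and of the 3302 remaining genes 157 and 324, or 14.6%. The class limits were set after the values were seen, and the shares were not tested against each other. A gene could enter the first class through the 1 hemisphere where it was high at 110 cells, while the class of 8918 genes was set on 8-cell values alone. Part of the contrast between the shares is therefore set by the limits.

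**Figure D3:**
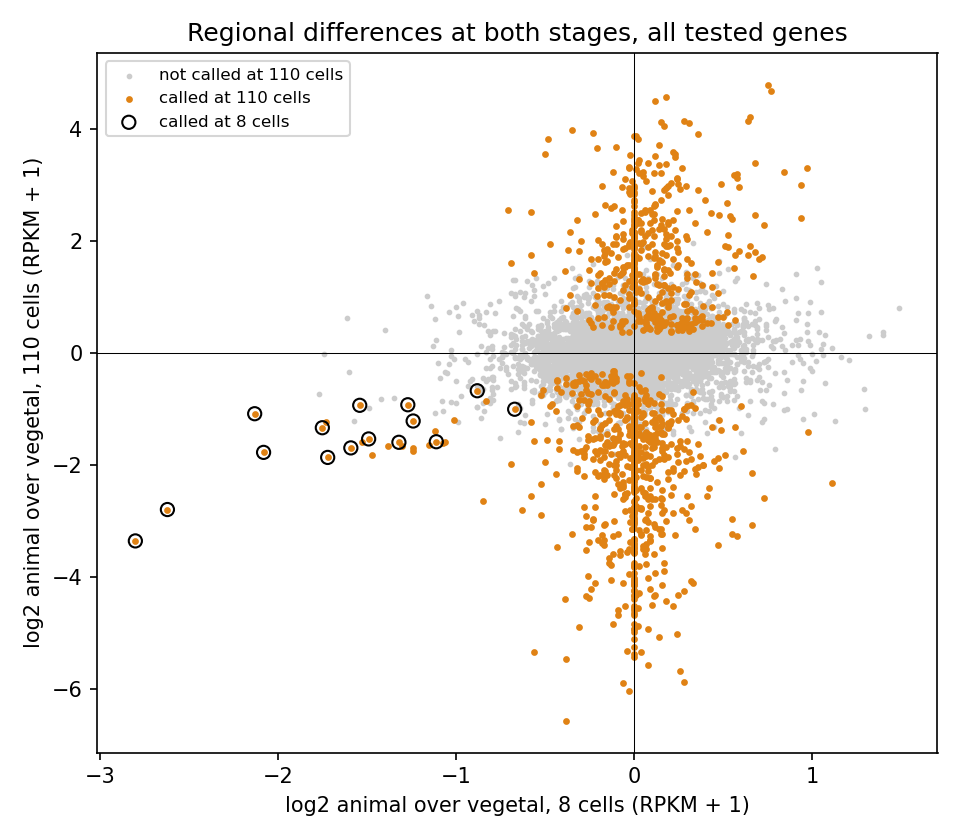
Log2 animal over vegetal difference of each tested gene at 8 cells (horizontal axis) and at 110 cells (vertical axis), on the log2(RPKM + 1) scale. Orange points are the 1163 genes called at 110 cells, and open circles are the 15 genes called at 8 cells, all in the lower left.

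Of the regional genes at 110 cells, 338 animal-higher and 594 vegetal-higher genes differed at least 2-fold. With the replicate number as a block 1824 genes were called, 911 animal-higher and 913 vegetal-higher. The vegetal library of replicate 5 showed genes at least 4-fold animal-higher in the other numbers at a median of 16.3% of the level in the animal library of its number, against 6.21% to 7.48% for the other numbers. In the reverse direction, the animal library of replicate 5 showed vegetal-higher genes at a median of 3.82% of the vegetal level, against 0% to 1.84%.

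Between the 8-cell and the 110-cell stage, 1721 genes rose and 1383 fell in whole embryos. Harore.CG.MTP2014.S911.g11803 (7072 to 8692), with no match named, rose from 1.79 ± 1.28 to 216 ± 40.6 RPKM (SD, n = 4), a 121-fold rise (log2 6.36 ± 0.34 SE, adjusted p = 4.45e-12), and Harore.CG.MTP2014.S172.g02982 (170746 to 175238, KH.C11.648) rose from 1.15 ± 1.34 to 147 ± 55.2 RPKM (log2 6.22 ± 0.39 SE, adjusted p = 4.03e-11). The largest falls were those of the vegetal-higher pair on scaffold S480. Harore.CG.MTP2014.S480.g12062 fell from 202 ± 9.07 to 19.3 ± 10.8 RPKM (log2 -3.49 ± 0.32 SE, adjusted p = 1.89e-08) and Harore.CG.MTP2014.S480.g14149 from 442 ± 16.3 to 48.5 ± 14.7 RPKM (log2 -3.21 ± 0.22 SE, adjusted p = 1.37e-10). In vegetal hemispheres their means fell less, from 422 ± 23.8 to 130 ± 63.8 and from 806 ± 138 to 287 ± 82.2 RPKM. Whole embryos at 110 cells thus lay near the animal hemispheres, at 10.9 ± 2.88 and 40 ± 9.58 RPKM, and the cause was not tested.

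The median log2 change was 1.13 among genes that rose and -0.88 among those that fell, and 447 rises against 30 falls reached 4-fold. Of the 15 genes that were vegetal-higher at 8 cells, 8 fell, 0 rose and 7 were not called. Of the 1721 genes that rose, 244 were animal-higher and 475 vegetal-higher at 110 cells, and of the 1383 that fell, 26 and 14. No gene with at least 5 RPKM in every 8-cell group was below 1 RPKM in every 110-cell group. Among 4090 tested genes whose note names the same best match as another gene, 712 rose and 302 fell, and as a set they rose relative to other genes (camera adjusted p = 0.0292, and 0.0291 with an estimated correlation). The set did not pass the test in animal hemispheres (adjusted p = 0.254, and 0.235 with an estimated correlation) or in vegetal hemispheres (0.0525 and 0.0957), and the difference between these comparisons was not tested. Without replicate 5 of every group 1989 genes were called in place of 3104. Which direction held more genes depended on the setting, with 1526 rises and 1556 falls after quantile normalization, 1342 and 1405 with a filter of 5 RPKM, and 1839 and 1289 after median-ratio rescaling.

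In animal hemispheres 908 genes rose and 748 fell between the stages. Harore.CG.MTP2014.S172.g02982 rose from 0.919 ± 0.506 to 300 ± 112 RPKM (SD, n = 4; log2 7.25 ± 0.39 SE, adjusted p = 4.42e-12). Harore.CG.MTP2014.S55.g11366 (218178 to 219259, KH.C2.1036) rose from 0.162 ± 0.323 to 173 ± 108 RPKM (log2 7.02 ± 0.48 SE, adjusted p = 2.26e-10), and at 8 cells it was above 0 in a single animal library. Harore.CG.MTP2014.S480.g12062 fell from 61.1 ± 14.9 to 10.9 ± 2.88 RPKM (log2 -2.37 ± 0.32 SE, adjusted p = 9.51e-06). Harore.CG.MTP2014.S29.g01910 (378298 to 378498), a model with a single coding exon and no match named, fell from 13.3 ± 1.61 to 2.74 ± 2.54 RPKM (log2 -2.27 ± 0.65 SE, adjusted p = 0.0212), a call that was lost without animal 110-cell replicate 4 (adjusted p = 0.0857) or 5 (0.0691), animal 8-cell replicate 5 (0.0516), replicate 4 (0.126) or 5 (0.0839) of every group, or with a pseudocount of 0.1 (0.064). Over all alternatives its adjusted p ranged from 0.00443 to 0.126. With the replicate number as a block 1453 genes rose and 1383 fell, and without replicate 5 of every group 912 were called in all. After quantile normalization 846 rose and 844 fell, with a filter of 5 RPKM 683 and 763, and after median-ratio rescaling 960 and 708.

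In vegetal hemispheres 1469 genes rose and 1397 fell. Harore.CG.MTP2014.S42.g07916 (246315 to 250245, KH.C1.224) was at 0 in all 4 vegetal libraries at 8 cells and at 112 ± 16.5 RPKM at 110 cells (SD, n = 4; adjusted p = 2.16e-12). That is at least 278-fold higher against a floor of 0.404 RPKM, which stands for 3 reads per library. Harore.CG.MTP2014.S80.g04926 (38960 to 39795), with no match named, rose from 0.227 ± 0.455 to 135 ± 64.6 RPKM (log2 6.73 ± 0.39 SE, adjusted p = 7.62e-12), and at 8 cells it was above 0 in a single vegetal library. Harore.CG.MTP2014.S588.g15354 (26196 to 27800, KH.S762.5) fell from 24.5 ± 2.2 to 5.97 ± 4.18 RPKM (log2 -2.16 ± 0.44 SE, adjusted p = 0.000743) and Harore.CG.MTP2014.S107.g13282 (69439 to 70611, KH.C3.710) from 37.7 ± 5.49 to 9.09 ± 6.03 RPKM (log2 -2.15 ± 0.35 SE, adjusted p = 6.35e-05).

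The lists of both hemispheres overlapped. Of the 748 genes that fell in animal hemispheres, 639 also fell in vegetal hemispheres, where independent lists would share 82, and 1 rose. Of the 908 that rose in animal hemispheres, 504 also rose in vegetal hemispheres, where independent lists would share 105, and 0 fell. No library was shared between these comparisons, but same-numbered animal and vegetal libraries deviated together and the spread was estimated in 1 fit. The lists are therefore not independent, and the counts for independent lists are not what chance would give here. With the replicate number as a block 2111 genes rose and 2272 fell in vegetal hemispheres, and without replicate 5 of every group 1690 were called in all. The larger direction turned here too, with 1363 rises and 1479 falls after quantile normalization, 1044 and 1400 with a filter of 5 RPKM, and 1723 and 1111 after median-ratio rescaling.

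**Figure D4:**
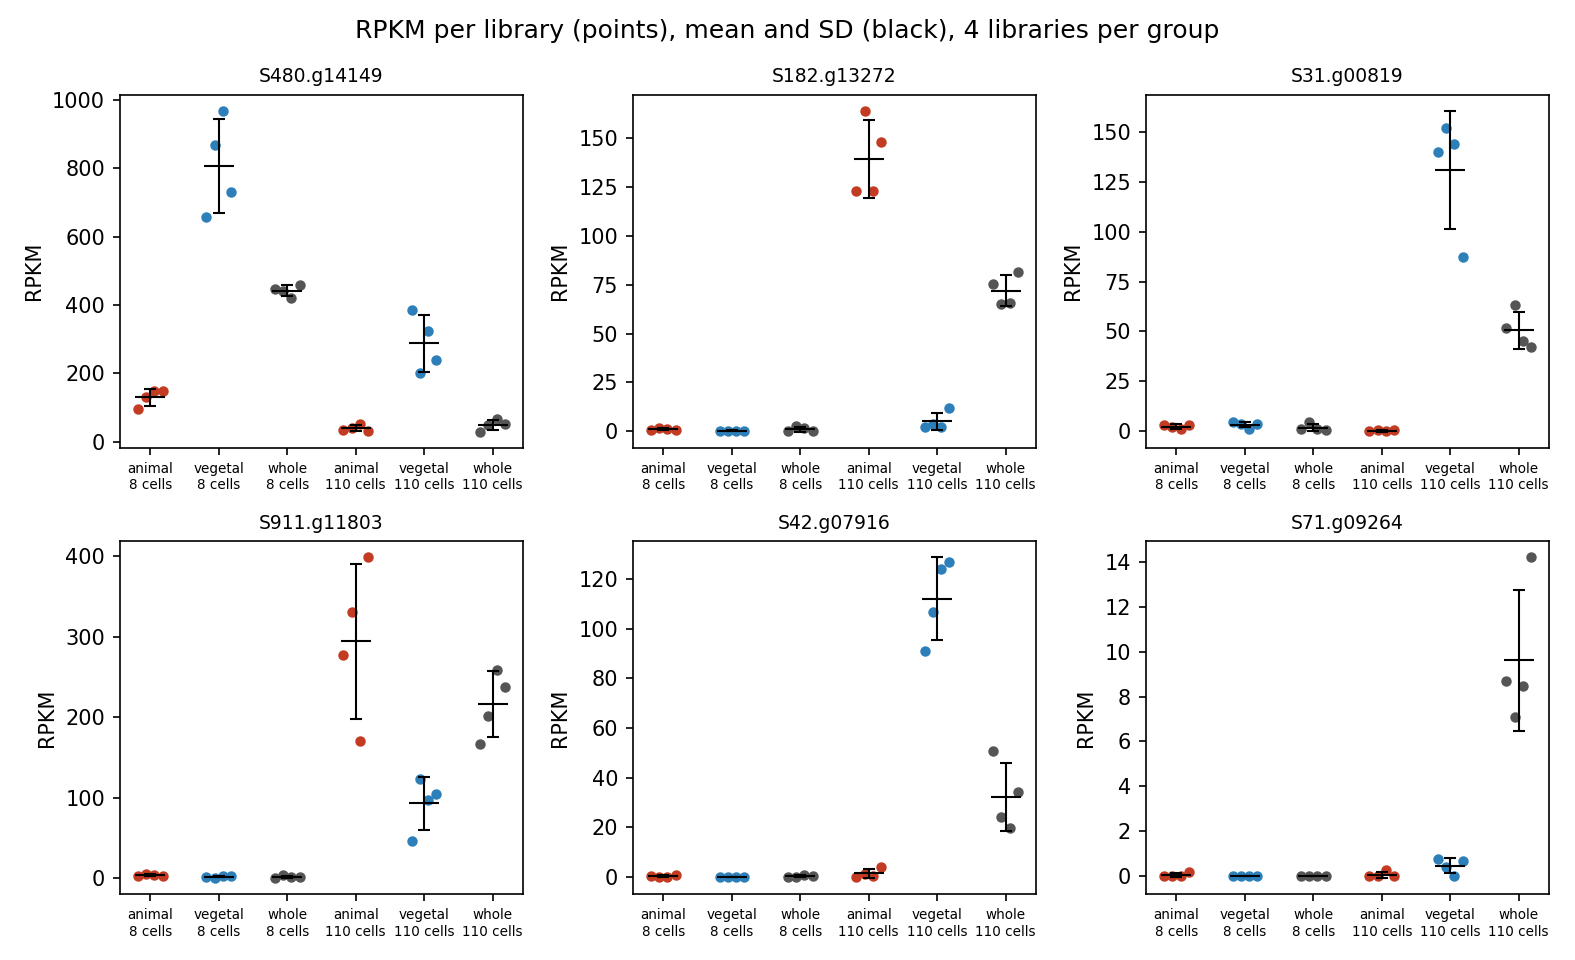
RPKM of 6 named genes in each library, with points for the 4 libraries of a group, a black bar for the mean and whiskers for the SD. The genes with identifiers ending S480.g14149, S182.g13272, S31.g00819, S911.g11803, S42.g07916 and S71.g09264 are shown, and the whole embryos at 110 cells stand above both hemispheres in the last, at 9.61 ± 3.14 RPKM.

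The difference between the hemispheres changed from the 8-cell to the 110-cell stage in 651 genes, 209 towards the animal and 442 towards the vegetal side. Of the 209, 197 rose in animal hemispheres and 10 fell in vegetal hemispheres, and of the 442, 438 rose in vegetal hemispheres and 4 fell in animal hemispheres. Harore.CG.MTP2014.S31.g00819 changed by log2 -6.18 ± 0.50 SE (adjusted p = 1.42e-08) and Harore.CG.MTP2014.S42.g07916 by -6.16 ± 0.52 SE (adjusted p = 2.19e-08). Towards the animal side, Harore.CG.MTP2014.S201.g00399 (129673 to 130643, KH.C1.1181) changed by 4.38 ± 0.83 SE (adjusted p = 0.00111) and Harore.CG.MTP2014.S146.g12031 (208956 to 211006, KH.L95.5) by 4.37 ± 0.94 SE (adjusted p = 0.00395). The former model lies on the same strand as Harore.CG.MTP2014.S201.g08639, which ends at 129546. At 110 cells Harore.CG.MTP2014.S201.g00399 and Harore.CG.MTP2014.S146.g12031 stood at 77.4 ± 46.3 and 132 ± 87.9 RPKM in animal hemispheres and at 4.03 ± 5.23 and 8.81 ± 13.5 RPKM in vegetal hemispheres (SD, n = 4). Genes off at 8 cells and on at 110 made up 105 of the 209 and 220 of the 442. Without replicate 2 or without replicate 5 of every group, 424 genes were called, and Harore.CG.MTP2014.S146.g12031 missed the threshold without replicate 2 (adjusted p = 0.109). With a pseudocount of 0.1 it missed it too (0.103), as did Harore.CG.MTP2014.S201.g00399 (0.0795), and over all alternatives the adjusted p ranged from 3.75e-05 to 0.109 and from 3.8e-05 to 0.0795.

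At the 8-cell stage no gene passed the test between whole embryos and the mean of their hemispheres. The limma test called 0 genes (1 in a fit of these groups alone), with 186 at an unadjusted p under 0.05, 85 higher and 101 lower in whole embryos. Here too the share is smaller than the 0.05 that would arise without any difference, so the absence of calls does not show that no gene differs. All 13 genes with a regional difference of at least 2-fold had a whole-embryo mean between those of the hemispheres.

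Whole embryos of the 110-cell stage differed from the mean of their hemispheres on the log scale in 83 genes, 74 higher and 9 lower. Harore.CG.MTP2014.S71.g09264 (100137 to 102395, best match KH.C2.957) stood at 9.61 ± 3.14 RPKM in whole embryos, 0.0676 ± 0.135 in animal and 0.474 ± 0.35 RPKM in vegetal hemispheres (SD, n = 4; log2 3.06 ± 0.18 SE, adjusted p = 6.03e-10). Its note names the same match as that of Harore.CG.MTP2014.S182.g13272, which stood at 139 ± 20 RPKM in the animal hemispheres. Harore.CG.MTP2014.S461.g13082 (42780 to 44665, KH.S589.4) stood at 23 ± 4.54 RPKM in whole embryos, 0.179 ± 0.248 in animal and 13.4 ± 2.7 RPKM in vegetal hemispheres (log2 2.54 ± 0.18 SE, adjusted p = 5.45e-09). In the other direction, Harore.CG.MTP2014.S196.g08088 stood at 0.212 ± 0.425 RPKM in whole embryos against 0.166 ± 0.332 and 7.65 ± 1.92 in animal and vegetal hemispheres (log2 -1.41 ± 0.33 SE, adjusted p = 0.0453), and Harore.CG.MTP2014.S105.g00556 at 2.6 ± 0.765 against 7.6 ± 4.36 and 9.54 ± 4.3 RPKM (log2 -1.32 ± 0.31 SE, adjusted p = 0.0468). The call of Harore.CG.MTP2014.S196.g08088 was lost without any single 110-cell library except whole-embryo replicate 3 (adjusted p = 0.197 without whole-embryo replicate 5), and that of Harore.CG.MTP2014.S105.g00556 without any except animal replicates 3 and 5, vegetal replicate 5 and whole-embryo replicate 3 (0.19 without whole-embryo replicate 2). Over all alternatives these adjusted p-values ranged from 0.00372 to 0.535 and from 0.0137 to 0.439.

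A whole embryo averages its hemispheres on the linear scale, so a regional gene can lie above the mean of log values. Of the 74 genes, 43 had a whole-embryo mean between those of the hemispheres. Of 932 genes with a regional difference of at least 2-fold, 885, or 95%, had a whole-embryo mean between the hemispheres. Tested against each hemisphere, whole embryos were above both in 10 genes, all of which rose between stages in whole embryos, and below both in 2, which fell. Those 2, Harore.CG.MTP2014.S114.g12204 (KH.C7.42) and Harore.CG.MTP2014.S61.g13859 (KH.S773.1), named after their values were seen, stood at 7.36 ± 1.63 and 5.55 ± 2.34 RPKM in whole embryos, 15.2 ± 3.69 and 12.5 ± 1.77 in animal and 14.2 ± 3.65 and 10.9 ± 2.75 RPKM in vegetal hemispheres (SD, n = 4). With the replicate number as a block 16 genes were above both. Fewer were above both without vegetal replicate 3 (6 genes), whole-embryo replicate 2 (5), 4 (5) or 5 (4), or replicate 2 (4), 3 (4), 4 (3) or 5 (1) of every group. With that block the contrast with the mean of the hemispheres called 118 higher and 59 lower genes, and after quantile normalization 68 higher and 24 lower. Without whole-embryo replicate 2 or 5, 47 and 48 genes were called, and without replicate 2, 4 or 5 of every group 29, 28 and 29.

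The share of the animal hemisphere that best placed whole embryos between their hemispheres was 57.3% ± 6.56 at 110 cells, with 49.5% to 63.5% over the 4 numbers (SD, n = 4). At 8 cells it was 46.2% ± 25.7, from 8.35% for replicate 2 to 64.6% for replicate 4, and it rested on 7 to 15 genes. Taken as a median over genes the share was 53.5% ± 13 at 8 cells, from 34.2% for replicate 2 to 62.4% for replicate 5, and 47.7% ± 4.33 at 110 cells (SD, n = 4), so which stage had the higher share depended on the summary. The shares describe RNA in RPKM units and no test was made between the stages.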

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

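The test on material carried by whole-embryo libraries was chosen only after its result was seen, and the tests on all 3 patterns were chosen after the patterns were noticed in these data.

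Over splits that ignore the replicate numbers, chance assignment of libraries was excluded for the comparisons between hemispheres and between stages. The real split was the only 1 of 35 with as many genes called in each: 15 genes against at most 0 for the hemispheres at 8 cells, 1163 against 117 at 110 cells, 3104 against 3 for the stages in whole embryos, 1656 against 0 in animal and 2866 against 4 in vegetal hemispheres. For the change between stages, tested on the 8 same-numbered differences, 715 genes were called against at most 1 in the other 34 of 35 splits. Where numbers pair the libraries, 8 splits part all 4 pairs, too few for a share under 0.05, and the highest other count among them was 0, 3, 0, 1 and 0 for the hemispheres at 8 and 110 cells, the stages in animal and vegetal hemispheres and the change between stages. The other splits leave some numbers on one side, so where the numbers pair the libraries chance assignment is not excluded.

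For whole embryos against the mean of the hemispheres at 110 cells, chance was not excluded, since 6 of 50 relabellings of the 12 libraries gave 83 genes or more. The highest gave 265, several times the real count. Relabellings can place animal or vegetal libraries under the whole-embryo label, and the regional difference of 1163 genes then enters the count. They do not show what chance alone gives, so the share of 6 in 50 cannot decide the question. At 8 cells the relabellings decide nothing, because with 0 genes called 50 of 50 give as many whatever the libraries hold, and the highest of the others was 195. Relabellings within numbers reached 953 genes at 110 cells and 0 at 8 cells. They exchange regions only and keep each number in every group, so the high counts at 110 cells point to region and not to number. Genes above both hemispheres numbered 10 in the real labelling and at most 3 in the other random relabellings, so 1 of 50 gave as many. Relabelled within numbers, the libraries gave up to 149, many times the real count, where hemispheres under the whole-embryo label bring the regional difference with them. The random relabellings ignore the numbers, and those within numbers bring in the regional difference. Neither shows what chance alone gives for this count, so chance is not excluded for these genes.

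Genes above both hemispheres in whole embryos at 110 cells formed the first pattern followed up. Selection of chance high values is argued against for the few genes selected without a number. In the number left out of the selection 10 of 12 values, 83.3% (exact 95% interval 51.6% to 97.9%), lay above both hemispheres. The selections without numbers 2, 3, 4 and 5 held 4, 4, 3 and 1 genes. The same genes recur among these values, and the interval treats them as separate. Material carried by whole-embryo libraries of both stages would show at 8 cells, where whole embryos had levels of at most 0.145 RPKM. This test was chosen after its result was seen, so it is not evidence against such material. Material carried by the whole-embryo libraries of 110 cells alone was not tested and stays open. A general delay of the hemispheres in switching genes on stays open. Among 85 other switched-on genes without a regional call, 23.5% ± 12.5 of values lay above both (SD, n = 4), from 10.6% to 36.5%. Libraries drawn alike would give 33.3%. That is not the chance rate here, since genes called above both or between the hemispheres were left out. No other biological explanation was tested, because the labels do not say when the hemispheres were separated.

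Transcripts that had fallen in both hemispheres were lower in whole embryos than in hemispheres at 110 cells, the second pattern. For 626 fallen genes without a regional call, log2 of whole over mean hemisphere RPKM was lower than for 6071 genes without a stage call (mean difference -0.14 ± 0.06 SD, below 0 in 4 of 4 numbers, one-sided exact permutation p = 0.0123, the smallest that 81 relabellings give). Scaling of the whole-embryo libraries would move the genes without a stage call alike. Those genes were selected by calls that use the same 110-cell libraries, so a shift could be partly hidden in them. The fallen genes were selected to have no called difference between animal and vegetal libraries. Whole embryos are then not exchangeable with the hemispheres, and the relabellings do not show what chance alone gives. The test therefore cannot decide on scaling, which stays open. Hemispheres behind whole embryos in the whole stage change could not be decided, since 341 risen genes differed from those without a stage call by -0.09 ± 0.13 SD (above 0 in 2 of 4 numbers, one-sided exact permutation p = 0.901). What sets the fallen transcripts apart stays open.

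Neighbouring genes called at 110 cells went the same way, the third pattern. Of 314 adjacent pairs with both genes called, 282 (89.8%) had the same direction, where shuffled directions gave 52.1%. Reads shared by close models do not account for all of it, since 80.4% of 138 pairs at least 1 kb apart went the same way. Neither do split models or tandem copies with the same best match, with 81.6% of 76 such pairs with different best matches (permutation p = 0.0001 for both, the smallest that 10000 shuffles give). Split models or tandem copies whose notes name different matches were not removed and stay open. The 97.2% among pairs under 1 kb apart may include shared reads. No biological explanation was tested, because the design holds none for gene order.

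Of 79 groups of 4 values examined, 12 had a value far from the other 3. In 6 of them the other 3 were at 0, which fixes the outcome, and in 2 further groups all 4 values were at 0. Of the remaining 71 groups 6 had such a value, where chance gives about 3.55, and no test was made of that difference. In vegetal libraries at 110 cells, replicate 5 stood apart at 28.8 RPKM for Harore.CG.MTP2014.S146.g12031 (others 0.466 to 4.7), at 11.8 for Harore.CG.MTP2014.S182.g13272 (others 2.19 to 3.65) and at 12134 genes with at least 1 RPKM (others 11714 to 11769). Whole-embryo replicate 3 at 110 cells was deeper, at 9.07 M reads (others 5.63 to 6.17). The mean log2 value of scaffold S964 was 8.86 in vegetal replicate 2 at 110 cells (others 7.91 to 7.95) and 7.37 in vegetal replicate 4 at 8 cells (others 7.67 to 7.72). In the remaining 6 groups a single library was above 0, for Harore.CG.MTP2014.S196.g08088 at 0.665 RPKM in animal replicate 2 and 0.849 in whole replicate 3 at 110 cells, Harore.CG.MTP2014.S201.g00399 at 0.667 in animal replicate 4 and Harore.CG.MTP2014.S55.g11366 at 0.647 in animal replicate 3 at 8 cells, Harore.CG.MTP2014.S71.g09264 at 0.27 in animal replicate 4 at 110 cells, and Harore.CG.MTP2014.S80.g04926 at 0.91 in vegetal replicate 5 at 8 cells.

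The animal against vegetal difference changed between the stages for 8 named genes by the limma interaction test. It gave Harore.CG.MTP2014.S104.g10185 at log2 -6.00 (adjusted p = 1.82e-08), Harore.CG.MTP2014.S182.g13272 at 4.03 (2.03e-05), Harore.CG.MTP2014.S201.g08639 at 3.89 (0.0103) and Harore.CG.MTP2014.S80.g04926 at -2.74 (0.00218). It also gave Harore.CG.MTP2014.S31.g00819 at -6.18 (1.42e-08), Harore.CG.MTP2014.S42.g07916 at -6.16 (2.19e-08), Harore.CG.MTP2014.S201.g00399 at 4.38 (0.00111) and Harore.CG.MTP2014.S146.g12031 at 4.37 (0.00395).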

How the results depend on the processing

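Alternatives for the genes above both hemispheres, for scaffold S964 and for the share of switched-on genes with a regional call were chosen after seeing the data. No named gene reversed its direction: over 638 values of 26 named results, 596 kept their side of the threshold and 42 did not, with the exceptions mostly among the genes lower in whole embryos. The stricter filter of 5 RPKM, which tests fewer genes, called 670 genes for the hemispheres at 110 cells, 394 for the change between stages, 53 for whole embryos against the hemispheres at 110 cells and 2 above both hemispheres. A fit of the compared groups alone, with fewer libraries, called 745 for the hemispheres at 110 cells and 1 and 30 for whole embryos at 8 and 110 cells. A 2-fold minimum left 1491 stage genes in whole embryos, 882 in animal and 1413 in vegetal hemispheres. The replicate block called 39 and 1824 genes for the hemispheres at 8 and 110 cells, 2836 and 4383 for the stages in animal and vegetal hemispheres, 177 for whole embryos at 110 cells and 16 above both hemispheres, and it changed no other count by over 1.5 times. Between the stages in whole embryos the block called 4601 genes against 3104, but there the numbers were not taken to pair the libraries, since the lowest same-number correlation was 0.08, although 4 of 4 libraries correlated best with their own number. Genes above both hemispheres numbered 4 with a pseudocount of 0.1 and 26 without a filter. The cause of the shifts with the block and the pseudocount was not tested. The animal share was 53.5% at 8 cells and 47.7% at 110 cells as a median over genes. Leaving out libraries or replicate numbers gave 7 to 17 genes for the hemispheres at 8 cells, 822 to 1121 at 110 cells, 1989 to 2954, 912 to 1763 and 1690 to 2880 for the stages in whole embryos, animal and vegetal hemispheres, 424 to 651 for the change between stages, 0 throughout for whole embryos at 8 cells, 28 to 106 at 110 cells, 1 to 10 above both hemispheres, and an animal share of 40% to 58.8% at 8 cells and 55.2% to 59.8% at 110 cells. The genes above both hemispheres fell to 1 without replicate 5 of every group. The scaffold S964 difference stayed between -1.28 and -1.42 at 8 cells and between -1.44 and -1.69 at 110 cells over its alternatives. The share of switched-on genes with a regional call was 75.5% to 77.8% leaving out a number and 80.3% rescaled. Neither scaling moved the median of all genes by over 0.1 on the log2 scale in any comparison, but quantile normalization turned the larger direction of the stage calls in whole embryos and vegetal hemispheres. The gene-list alternative and the count model were not run, because no list reached 5 members and no counts were used. Shallow vegetal libraries limit what can be said of genes near the 3-read floor, which was 0.314 to 0.648 RPKM there for 1.5 kb of exons. The floor is higher for shorter models. Harore.CG.MTP2014.S29.g01910 (378298 to 378498) and Harore.CG.MTP2014.S196.g08088 (147651 to 147884) are short, so their RPKM values stand for fewer reads than the same values in a longer model.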

Other observations

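All genes in this part were chosen after their values were seen, and no further test was made. The 10 genes above both hemispheres in whole embryos at 110 cells had low levels throughout, with means of 1.25 to 9.61 RPKM in whole embryos, at most 0.393 RPKM in animal and at most 2.58 RPKM in vegetal hemispheres (n = 4). Of these, 6 were off at 8 cells and on at 110.

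Of the 15 genes that were vegetal-higher at 8 cells, 6 lie on 3 scaffolds. Harore.CG.MTP2014.S126.g14611 (111249 to 111749) lies inside Harore.CG.MTP2014.S126.g01852 (110722 to 221780) on the other strand, and the libraries do not keep strand. They stood at 433 ± 76.1 and 24.8 ± 4.17 RPKM in vegetal and at 130 ± 11.7 and 7.56 ± 1.26 RPKM in animal hemispheres at 8 cells (SD, n = 4). Harore.CG.MTP2014.S138.g03243, on another scaffold, has the same best match as the second, KH.C9.36, and stood at 23.2 RPKM in vegetal and 8.64 RPKM in animal hemispheres.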
